A study of Mus musculus with 2 samples.

How the data were processed

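Aortic roots and ascending aortas of 8-week-old mice were digested with Liberase and elastase, sorted to exclude debris and captured on the 10x Genomics Chromium platform with the 3' version 3 chemistry, per the labels' protocols. Tissue of several mice was pooled into each of 2 libraries, 1 from mice with a heterozygous Tgfbr2 G357W change, named LDS for Loeys-Dietz syndrome, and 1 from wild-type (WT) mice. The labels give the LDS library as a pool of both sexes and the WT library as male, while the labels' protocols describe groups of sex-matched animals. Cell Ranger 6.1.2, Seurat without a version and the mouse build mm10 are named, per the submitters' processing notes, which give no role or order for them.

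The deposited table held whole numbers for 18251 genes in 11613 cells, and these values were treated as a depth-adjusted score rather than as raw counts of molecules. No source used here states the adjustment. It was inferred from the values, because the cell totals lay within the narrow range of 9277 to 12650, the highest value was 2342 and every gene was present in at least 5 cells, a pattern that Seurat's SCTransform step also leaves. The filters on cells, any doublet or free RNA step and the gene annotation behind the deposited score were not given in the sources used here. The molecule depth of the libraries was therefore unknown, no count model was fitted, and no counting interval was put on gene levels. The planned count intervals and TMM scaling assumed raw counts and were not computed.

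Each barcode ended in 1 of 2 suffixes, which formed barcode set 1 with 6460 cells and barcode set 2 with 5153 cells, and 5 barcodes occurred in both sets. No header or label ties a suffix to a library. Neither the order of the suffixes nor any measured gene was used to assign a genotype, so the planned LDS against WT comparisons were not made. The table was treated as 1 sample, with no test and no p-value, as had been fixed before the data were examined for a table without such a map. Values of each barcode set are given only as a description of how far they differ within the table.

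Cells with at least 500 genes and at most 10% mitochondrial values were kept, which removed 0 cells. Doublets were scored with Scrublet within each barcode set in scanpy 1.11.5. It marked 19 cells (0.164%), few for a table of this size, and whether the caller failed or doublets had been removed before deposit was not known. These 19 cells were left out, 11594 cells were kept, and unmarked doublets are likely to remain. For clustering only, values were scaled to 10000 per cell, log-transformed and reduced to 30 principal components of 2000 variable genes. A graph of 15 neighbours was clustered with the Leiden method at resolution 1 and seed 0, in Python 3.11.15 with igraph 0.11.9, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. No integration of the barcode sets was applied.

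Clusters were named X-like from 22 marker sets fixed before the data were examined. A name required at least 75% of the measured markers, and at least 3 of them, to be seen in at least 25% of the cluster's cells at a mean above the average over clusters. Clusters without a name were clustered again at resolution 0.2 with parts of at least 50 cells. These naming thresholds and the second clustering were set after the clusters had been seen. They left cluster 4 unnamed, with 9.11% of the cells of set 1 and 10.0% of set 2, and the remainder of cluster 14, with 2.56% and 1.19%.

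Levels are means of the deposited score over the cells of a class. A difference between classes is log2 of the ratio of these means, with no further scaling and a pseudocount of 0.01, which understates differences of low genes. The 35 gene lists were fixed before the data were examined and 620 of their 632 genes were measured, as were 175 of 202 marker genes. A list is described by the median log2 ratio of members with a summed value of at least 10, and by the percentile of that median among 10000 random lists of the same size matched on level in 20 bins. Named genes are Tgfbr2 and Ccl2 in each class, and 2 to 4 members of a list with the highest level or the largest ratio in the list's direction. The part of that rule that used genotype folds could not be applied. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only. For shares of cells with Ccl2, each cell was thinned to a total of 9000. The classes were formed from the same values that were then compared. Some reported lists hold class markers, and where these moved a list its values are also given without them.

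The steps for ratios and lists were tested on simulated data for the fibroblast-like against smooth-muscle-like comparison over 18251 genes, with 200 genes altered. Each gene was drawn on its own as a Poisson sum per class, and altered genes had a summed value of at least 50. Spread between cells, co-expression within lists and the depth adjustment were therefore not covered. Planted folds of 2, 0.5, 4 and 0.25, each in 50 genes, returned median log2 values of 0.95, −0.88, 1.93 and −1.81, with 100% in the planted direction. A list planted at a fold of 2 reached percentile 100. Of 100 unaltered lists, 8 lay outside the middle 95% of random lists, and their median percentile was 59.2, so single percentiles near the ends of the range are approximate.

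Gene symbols were matched to the GRCm38.p6 annotation, in which 16693 of the 18251 symbols (91.5%) were found. The alternatives covered the cell filter, doublet removal, clustering resolution, separate clustering of the barcode sets, scaling, thinning and the minimum value of list members. A further 5 were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.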

Results

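Single-cell transcriptomes were collected from the aortic root and ascending aorta of 8-week-old mice, in a study of chemokine-expressing adventitial fibroblasts in Loeys-Dietz syndrome, an inherited disorder of TGF-beta signalling with aortic aneurysm. The labels describe 2 pooled libraries, 1 LDS library from mice heterozygous for Tgfbr2 G357W and 1 WT library. The table held 11613 cells in barcode set 1 (6460 cells) and barcode set 2 (5153 cells). No header or label ties either set to a library, and neither was assigned to a genotype. The differences between LDS and WT that the design asks for were therefore not measured, and the cell classes of the whole table are described instead, without replicates. Cell totals of the adjusted values had a median of 10526 in set 1 and 11453 in set 2, and a median of 3134 and 3537 genes was seen per cell. The original depth was unknown.

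Smooth-muscle-like cells made up most of the tissue, with 8023 of 11594 kept cells (69.2%, 95% interval 68.4 to 70.0%). Fibroblast-like cells followed with 1727 cells (14.9%, 14.3 to 15.6%), macrophage-like cells with 368 (3.17%, 2.86 to 3.51%), endothelial-like cells with 113 (0.975%, 0.804 to 1.17%) and mesothelial-like cells with 33 (0.285%, 0.196 to 0.399%). The endothelial-like cells were led in part by the lymphatic genes Ccl21a and Mmrn1. Cluster 4, with 1104 cells (9.52%), stayed unnamed and was made of parts led by Myoc and Ccl19, by the cartilage-associated genes Chad, Cilp2 and Comp, by Npy and Cxcl10, and by Epyc and Vcan. Each of these 4 parts met 5 or 6 of 10 valve interstitial markers, below the 75% needed for a name. Other classes came as close or closer. The part led by Chad matched fibroblast best, with 8 of 14 markers, and the part led by Myoc met 7 of 14. The part led by Epyc met 6 of 10 smooth muscle markers and the part led by Npy 4 of 9 chondrocyte markers. The remaining 226 cells of cluster 14 (1.95%) were in a part led by genes such as Ankrd1 and Plvap and a part led by Cthrc1, Cytl1 and Pecam1. Endothelial was the closest class of both, with 3 and 5 of 11 markers, and fibroblast the next, with 3 and 6 of 14. They stayed unnamed and are not in the endothelial-like share or comparisons. Fibroblast-like cells formed 13.02% of set 1 and 17.3% of set 2, and smooth-muscle-like cells 70.8% and 67.2%. No T, NK or B cell class was found. Digestion, sorting and pooling can all set such shares.

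Which cells carried Ccl2, a chemokine that recruits monocytes, was the first question. Ccl2 lies on chromosome 11 at 82035577 to 82037452 of GRCm38.p6 and is annotated as protein coding. Macrophage-like cells had the highest level, with a mean of 22.4 (19.1 in set 1, 27.3 in set 2), and held 88.0% of the summed Ccl2 of the table with 3.17% of its cells. Fibroblast-like cells had a mean of 0.206 (0.220 and 0.192), smooth-muscle-like cells 0.0454, endothelial-like cells 0.159 (0.218 and 0.103), mesothelial-like cells 0.0606 (0.118 and 0), cluster 4 0.311 (0.514 and 0.0795) and cluster 14 0.204 (0.212 and 0.180). On the log2 scale Ccl2 was 1.96 higher in fibroblast-like than in smooth-muscle-like cells (2.00 and 1.94 in the sets) and 6.70 higher in macrophage-like than in fibroblast-like cells (6.37 and 7.08). Whether tissue digestion raised Ccl2 or other chemokines in macrophage-like cells was not tested, so these levels describe digested tissue.

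After thinning, Ccl2 was seen in 69.8% of macrophage-like cells (64.9 to 74.5%), 5.56% of fibroblast-like cells (4.53 to 6.75%), 3.44% of smooth-muscle-like cells (3.05 to 3.86%), 6.19% of endothelial-like cells (2.53 to 12.3%) and 5.62% of cluster 4 (4.33 to 7.14%), with 7.99% of cluster 4 in set 1 and 2.91% in set 2. Without thinning the fibroblast-like share was 6.08%. C1qa, a macrophage complement gene used as a measure of free RNA, was seen in 4.81% of fibroblast-like cells (3.85 to 5.92%) and 4.33% of smooth-muscle-like cells (3.89 to 4.79%). Macrophage-like cells had a C1qa mean of 52.7, above their Ccl2 mean of 22.4. At a value of 2 or more, 2.20% of fibroblast-like cells (1.56 to 3.01%) held Ccl2, against 0.199% of smooth-muscle-like cells (0.114 to 0.324%). Fibroblast-like cells were not distinct from cluster 4 (2.26%, 1.47 to 3.32%), endothelial-like cells (2.65%, 0.551 to 7.56%) or cluster 14 (1.33%, 0.275 to 3.83%). At that value 0.579% of fibroblast-like cells (0.278 to 1.06%) held C1qa. Lyz2, another macrophage gene, was held by 2.43% of fibroblast-like cells (1.76 to 3.27%) and 0.636% of smooth-muscle-like cells (0.474 to 0.835%), so it showed a class difference too. Median totals were 10223 in fibroblast-like and 11265 in smooth-muscle-like cells. No class that should lack Ccl2, such as B cells, was available for comparison.

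**Figure D1:**
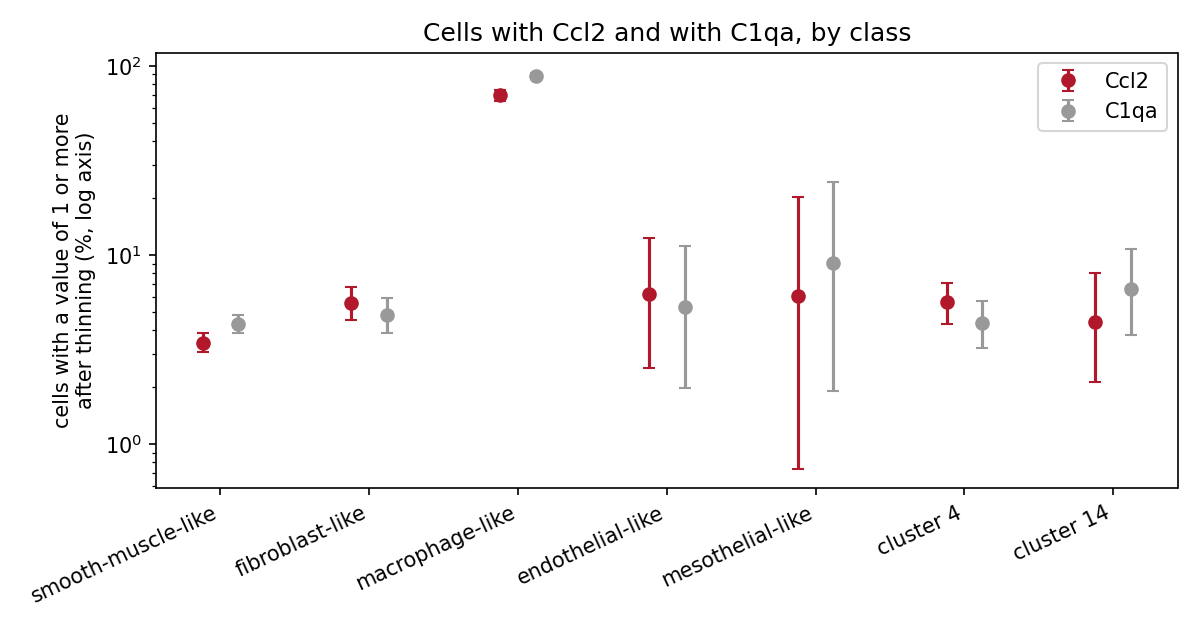
Percent of cells with a value of 1 or more for Ccl2 (red) and C1qa (grey) after thinning to a total of 9000, on a log axis, for each class on the horizontal axis. Points are shares over both barcode sets and bars are exact 95% intervals. Macrophage-like cells stand at 69.8% for Ccl2, and fibroblast-like cells at 5.56% for Ccl2 and 4.81% for C1qa.

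Tgfbr2, the type II TGF-beta receptor gene altered in the LDS mice, lies on chromosome 9 at 116087695 to 116175363 of GRCm38.p6. Its level was lowest in smooth-muscle-like cells at 0.534 (0.493 in set 1, 0.587 in set 2) and was 1.30 in fibroblast-like, 2.61 in macrophage-like, 1.97 in endothelial-like and 1.27 in mesothelial-like cells, 1.59 in cluster 4 and 0.726 in cluster 14. Tgfbr2 was 1.27 higher on the log2 scale in fibroblast-like than in smooth-muscle-like cells (1.36 and 1.14). Tgfbr1, the partner type I receptor, chosen after its values were seen, was instead lower in fibroblast-like cells (log2 −0.76), with means of 0.531 and 0.906. The values do not tell the mutant from the normal Tgfbr2 transcript.

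How fibroblast-like and smooth-muscle-like cells divided the matrix and signalling genes of the aortic wall was examined next. Fibroblast-like cells were higher for 16 of 17 fibrillar and associated collagens in both barcode sets (list median log2 1.83), with Col5a3 at 4.51 and Col11a1 at 4.48. Of 20 elastic fibre genes, 16 were higher in both sets (median 1.16), led by the fibulins Fbln1 (6.15) and Fbln2 (5.22), while Eln, the elastin gene, was lower in fibroblast-like cells (log2 −0.59, means 20.05 and 30.1). Mfap4, a microfibril-associated gene, stood at 22.4 and 18.2. Matrix proteases and inhibitors were higher for 15 of 20 genes (median 1.35), with the stromelysin Mmp3 at 4.74 and the inhibitor Timp2 at 2.17. Fbln1 means were 14.1 and 0.188. Both lists hold markers that were used to name the classes. Without these markers, a choice made after seeing the data, 13 of 14 collagens (median 1.69) and 15 of 19 elastic fibre genes (median 0.96) were higher in fibroblast-like cells.

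TGF-beta and BMP pathway components went both ways, with 19 of 32 higher and 10 lower in fibroblast-like cells (median 0.33, percentile 99.9 among random lists). The BMP family member Gdf10 (5.24) and the activin antagonist Fst (4.35) were higher, and the inhibitor of differentiation Id3, the member with the highest level, stood at 0.30. Lipid handling genes were higher for 12 of 18 (median 0.35), including Apoe (4.83) and lipoprotein lipase Lpl (5.26). Unfolded protein and integrated stress genes were higher for 19 of 22 (median 0.77), with the endoplasmic reticulum chaperones Hsp90b1 at 1.18 and Hspa5 at 0.64.

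Immune and inflammatory genes stood on the fibroblast side. Of 29 measured chemokines and cytokines, 22 were higher in fibroblast-like cells in both sets (median log2 1.61), with Il33 at 5.70, Il6 at 5.22, the neutrophil chemokine Cxcl1 at 3.76 and Cxcl12 at 1.61. Complement genes were higher for 12 of 15 (median 3.04), including C3 (7.20) and the inhibitor Serping1 (3.39). NF-kappaB targets were higher for 19 of 21 (median 1.89), with Tnfaip6 at 5.50, Icam1 at 5.17 and Ier3 at 0.61, and interferon response genes for 22 of 23 (median 0.80), with Ly6e at 5.42 and Ifitm3 at 2.10. Immediate-early genes, which tissue digestion also induces, were higher for 19 of 27 (median 0.48), with Cebpd at 2.39 and Junb at 0.86, while Fos stood at 69.8 and 76.8. Heat shock genes, another stress list, were instead lower in fibroblast-like cells for 9 of 14 (median −0.63, percentile 0.31). Percentiles among random lists were 100 for chemokines, complement and NF-kappaB targets and 99.9 for immediate-early genes.

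MHC class II genes, which present antigen to T cells, went the other way. All 7 measured members were lower in fibroblast-like than in smooth-muscle-like cells in both sets (median log2 −1.85), with Cd74 at −2.37 (means 0.241 and 1.29), H2-Ab1 at −2.09 and H2-Aa at −1.67. The difference was uneven over smooth-muscle-like sub-clusters made without the list genes, with mean Cd74 from 0.173, below the fibroblast-like mean, to 8.05. Macrophage-like cells had a Cd74 mean of 98.3. The direction held only with the unnamed clusters kept apart, since counting them as fibroblast-like, a choice made after seeing the data, gave a median of 1.29.

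Smooth-muscle-like cells were higher for adhesion and energy genes. Adhesion and integrin genes were lower in fibroblast-like cells for 12 of 20 and higher for 7 (median log2 −1.37), with integrin alpha 8, Itga8, at −2.88, filamin A, Flna, at −2.57 and Itgb1 at −1.39. Lower in fibroblast-like cells were also 19 of 23 glycolysis and hypoxia genes (median −0.59), with Gapdh at −0.59, 27 of 28 nuclear-encoded oxidative phosphorylation genes (median −0.39), with Cox4i1 at −0.55, and 13 of 13 mitochondrial-encoded genes (median −0.67), with mt-Nd4 at −0.88 and mt-Co2 at −0.50. The median of all 15987 genes compared was −0.08. The contractile list, of which 9 of 18 members were markers used to name the smooth-muscle-like class, had a median of −3.17. Without these markers the median was −3.09, with 9 of 9 lower in fibroblast-like cells in both sets. Both values are given for scale only.

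**Figure D2:**
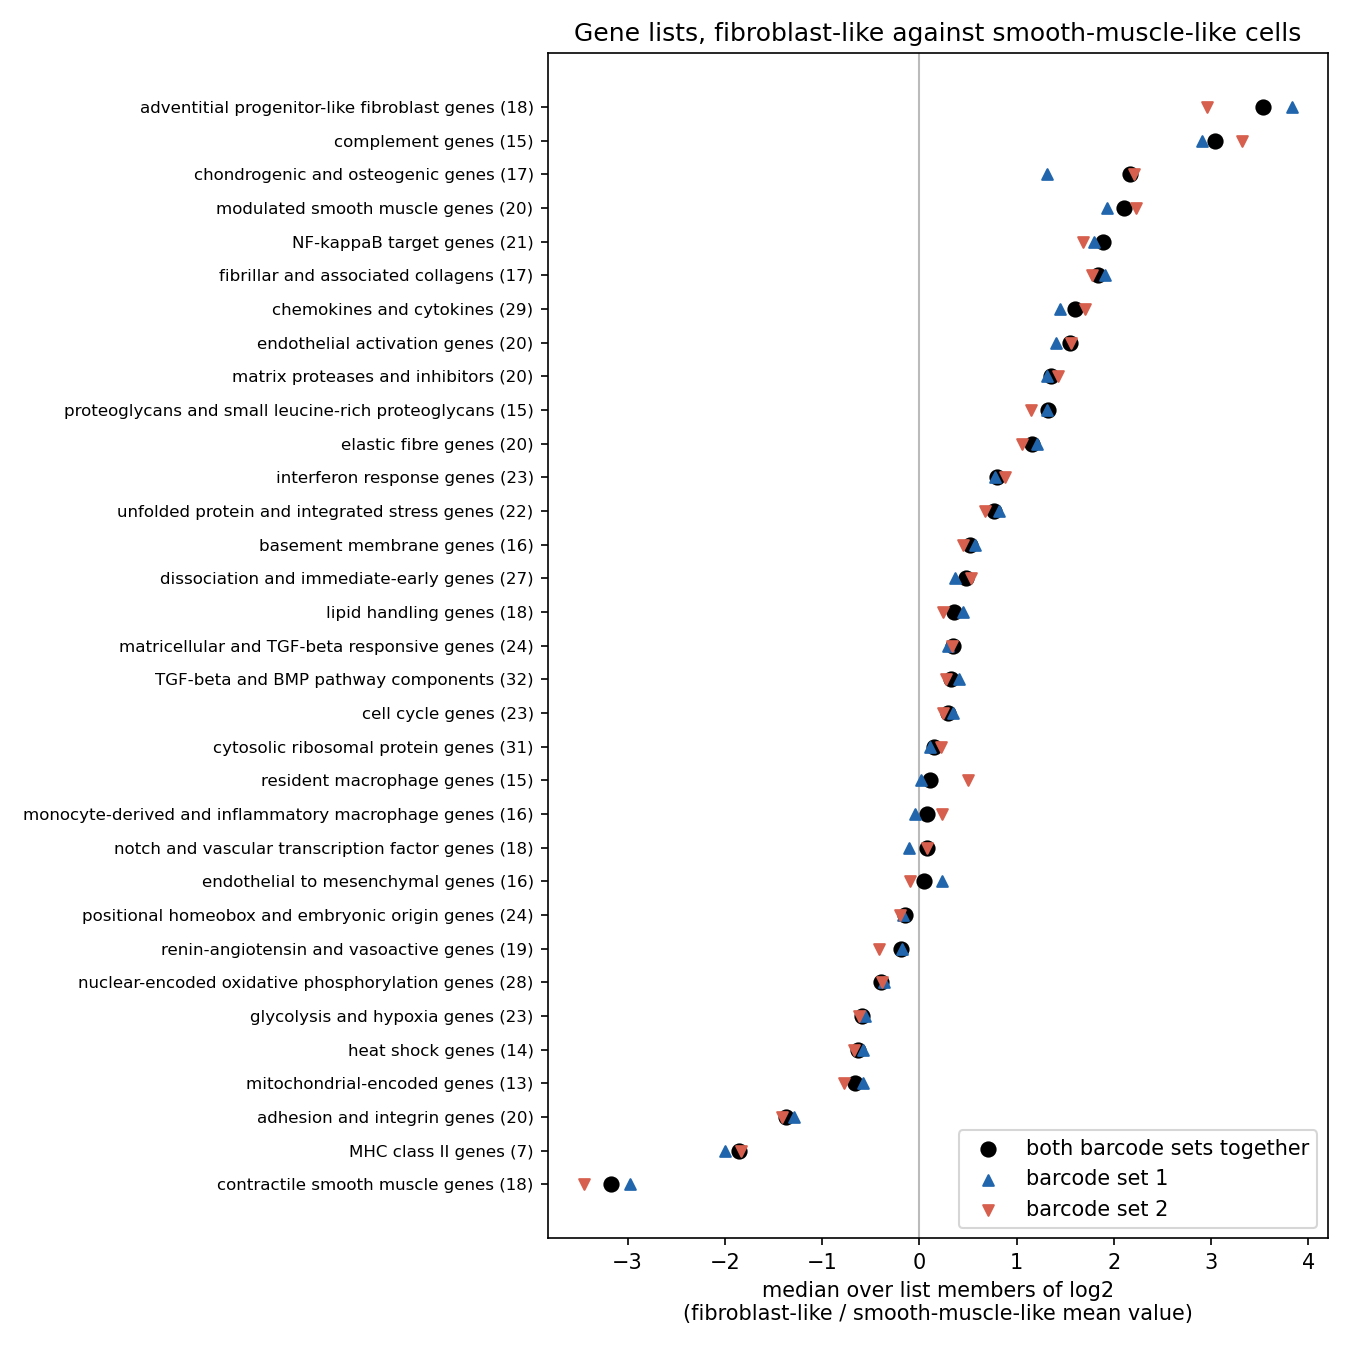
Median log2 ratio of fibroblast-like over smooth-muscle-like mean values for the fixed gene lists other than the haemoglobin and sex-linked genes, with the number of measured members in brackets. Circles are both barcode sets together, upward triangles set 1 and downward triangles set 2. Complement genes stand at 3.04 and MHC class II genes at −1.85.

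Macrophage-like cells were set against fibroblast-like cells to place the chemokines of the wall. Of 29 chemokines and cytokines, 16 were higher in macrophage-like cells in both sets and 12 lower (median log2 1.86), with Il1b at 9.50, Ccl4 at 8.95 and Cxcl2 at 8.92. NF-kappaB targets were higher for 15 of 21 (median 1.08), including Tnfaip3 (4.57) and Nfkbia (2.53), and MHC class II genes for 10 of 10 (median 6.59), including H2-Aa (8.91) and Cd74 (8.61). Cell cycle genes were higher for 21 of 23 (median 3.61), among them the proliferation genes Ube2c (6.15) and Mki67 (5.97) and the inhibitor Cdkn1a (1.69). TGF-beta and BMP components were lower for 26 of 31 (median −1.59), but Bmp2 (2.82), Tgfb1 (2.11) and Tgfbr2 (1.06 in set 1, 0.93 in set 2) were higher, and Id2 stood at −0.23.

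Endothelial-like cells, with 113 cells, carried endothelial activation genes above fibroblast-like cells for 17 of 21 members (median log2 1.91), or 16 of 20 without a class marker (median 1.62), including Selp (6.81), the nitric oxide synthase Nos3 (6.79) and the flow-responsive factor Klf2 (1.33). The class was named by endothelial genes, so these values are given for scale only. A contrast with fibroblast-like cells does not show whether endothelial-like cells were activated. Chemokines and cytokines were lower for 20 of 26 (median −1.22), with Cxcl12 at −1.69 and Cxcl16 at 0.74. TGF-beta and BMP components were split, 13 higher and 13 lower of 31 (median 0.05, or −0.01 without a class marker), with Bmp6 at 5.40, Tgfbr2 at 0.60 and Id3 at −0.20. Ccl2 stood at −0.35 (−0.01 and −0.83), and its direction turned under 4 alternative settings.

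Cluster 4 was set apart from fibroblast-like cells by MHC class II genes, higher for 7 of 7 (median log2 4.45, 5.70 in set 1 and 3.17 in set 2), with H2-Aa at 4.85, H2-Ab1 at 4.76 and Cd74 at 4.45. NF-kappaB targets were higher for 12 of 21 (median 0.49), with Nfkbia at 1.68 and Ier3 at 0.96, and complement genes lower for 11 of 15 (median −1.76), with C1s1 at −4.30. TGF-beta and BMP components had a median of 0.07, with Bmp2 at 3.03 and Tgfbr2 at 0.29. Chemokines and cytokines were split, 7 higher and 9 lower of 29 in both sets (median 0.11, against 0.18 over all genes compared), although Cxcl10 stood at 3.72. Ccl2 (0.57) and Cxcl1 (0.81) were higher in set 1 (1.19 and 1.47) and lower in set 2 (−1.17 and −0.36). The part led by Npy and Cxcl10 came mostly from set 1, with 274 of its 325 cells.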

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

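The settings that cluster without the list genes, count the unnamed clusters as fibroblast-like, use either barcode set alone or leave class markers out of the lists were chosen after the results were seen, and the others were planned. Over 16 settings and 114 results, 1013 of 1138 values stayed within the 95% interval of a share, or within the gap between the barcode sets or 0.1 on the log2 scale, whichever was larger, 108 moved further with the same sign and 17 changed sign. This leaves out 3 settings that could not test it, omission of a cell filter that had removed 0 cells and either barcode set alone, since the limit was set by the gap between the sets. For the values below the cause was not tested. Depth limits low genes throughout, and no setting recovers it. No paired analysis was possible because each group has 1 library and the barcodes name neither. Leaving out a library was not possible, and TMM scaling was not run because the values were not raw counts.

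Ratios below are log2, fibroblast-like over smooth-muscle-like unless stated. With the unnamed clusters counted as fibroblast-like, the share of that class was 26.4%, and medians were 2.12 for chemokines, 1.38 for collagens, 2.55 for complement, 0.55 for TGF-beta and BMP components and 1.29 for MHC class II genes. Ccl2 was then 2.19, Mfap4 −0.19, Cd74 0.73, H2-Ab1 1.29, H2-Aa 1.80 and the median of all genes 0.028, Id2 was 0.16 in macrophage-like over fibroblast-like cells, and the endothelial-like over fibroblast-like TGF-beta and BMP median was −0.019. At Leiden resolution 0.5, the fibroblast-like share was 18.5%, collagens 1.65, elastic fibre genes 1.33, TGF-beta and BMP components 0.48, MHC class II genes −1.47 and Ccl2 1.79, and the endothelial-like TGF-beta and BMP median was −0.024. Lists without class markers gave 1.69 for collagens and 0.96 for elastic fibre genes, and −0.013 for TGF-beta and BMP components in endothelial-like over fibroblast-like cells.

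Further MHC class II medians were −2.22 with the stricter cell filter, −1.49 with members of a summed value of at least 1, and −2.05 when clustered without list genes. Endothelial-like over fibroblast-like Ccl2 was 0.021 with the stricter filter, 0.069 without doublet removal, 0.036 at resolution 2 and 0.065 when clustered without list genes. Clustering each set on its own gave an endothelial-like share of 1.22%. Set 1 alone held 70.8% smooth-muscle-like and 13.02% fibroblast-like cells, with an endothelial-like TGF-beta and BMP median of −0.039. Set 2 alone held 67.2% and 17.3%, and in it cluster 4 over fibroblast-like cells was −0.21 for chemokines, −1.17 for Ccl2 and −0.36 for Cxcl1. The same chemokine median was −0.053 after thinning and −0.11 with members of a summed value of at least 50, and the TGF-beta and BMP median of cluster 4 was −0.0019 after thinning. The fibroblast-like share with Ccl2 was 2.20% at a value of at least 2.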

Other observations

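The tests of free RNA and of the sex-linked genes were chosen after the results had been seen, and those of doublets, of the immediate-early response and of depth were written before. Fibroblast-like cells formed 3 clusters, none of them confined to 1 barcode set. Cluster 6, with 960 cells, was led by F3, Hsd11b1 and Gdf10, cluster 9, with 492 cells, by Scara5, Pi16 and Ly6a, which mark adventitial progenitor-like fibroblasts, and cluster 15, with 275 cells, by Inmt, Dpep1 and Tcf21. Mean Ccl2 was 0.149, 0.307 and 0.222 in these clusters, so no cluster held most of it. In cluster 9 it was 0.440 in set 1 and 0.159 in set 2, and in cluster 15 it was 0.0687 and 0.361. Il6 was highest in cluster 6, at 0.966, against 0.203 in cluster 9. Interferon response genes were higher in cluster 9 than in cluster 6 for 17 of 22 members in both sets (median log2 0.58), and matricellular and TGF-beta responsive genes lower for 14 of 24 (median −0.68).

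Over all kept cells, Xist was seen in 21.7% and the Y-linked genes Ddx3y and Eif2s3y in 54.0% and 37.0%, values that are given for the pooled table only. MHC class II values in smooth-muscle-like cells were uneven, with mean Cd74 from 0.173 to 8.05 over 15 sub-clusters. Fibroblast-like sub-cluster 10, with 106 cells, had means of 165.7 for Acta2 and 22.9 for Myh11. The other fibroblast-like sub-clusters reached at most 40.1 and 3.95. It also had the highest median of genes (4068.5) and of totals (11757) among them. Doublets with smooth-muscle-like cells were not tested there, and these cells stayed in the fibroblast-like class.

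Higher Ccl2 in fibroblast-like than in smooth-muscle-like cells rested on few cells, since 43 fibroblast-like cells with a value of 2 or more, 20 in set 1 and 23 in set 2, held 82.5% of the summed Ccl2 of the class. The other fibroblast-like cells had a mean of 0.0368 (0.0415 and 0.0324), a level that free RNA could give. A low mean follows in part from leaving out the high cells. The 0.0454 of smooth-muscle-like cells is not cut in that way, as it includes 20 cells with a value of 2 or more. As the source of the higher Ccl2 in fibroblast-like cells, free RNA from macrophage-like cells would keep the ratio of Ccl2 to C1qa. Over the class that ratio was 6.28 times the macrophage-like one (8.28 and 4.72 in the sets). It was above the macrophage-like one in smooth-muscle-like cells too (means 0.0454 and 0.0570, against 22.4 and 52.7). The depth adjustment before deposit could also have altered it, so it is no firm reference. Doublets would bring macrophage transcripts, but 4.65% of the 43 cells (0.568 to 15.8%) reached a summed value of 10 for C1qa, C1qb, C1qc and Lyz2, against 93.8% of macrophage-like cells. The 41 cells below that sum, which can still hold some macrophage RNA, had more Ccl7 (3.70 in set 1 and 6.81 in set 2, against 0.284 and 0.593), Cxcl1 (4.15 and 11.5, against 1.89 and 2.02) and Il6 (2.10 and 1.67, against 0.463 and 0.851) than the other fibroblast-like cells. A response to tissue digestion stays open, because 16 of 27 immediate-early genes were higher in the 43 cells in both sets and 2 lower, and the fold was 2.22 among cells in the lowest quartile of immediate-early expression but 2.45 in set 1 and 0.781 in set 2, where 70 fibroblast-like cells were left. The 43 cells were picked by Ccl2 itself, and of 25 other chemokines and cytokines 13 were higher in them in both sets and 6 lower. Sub-clusters of fibroblast-like cells made without the list genes did not set such cells apart. The genes left out include Ccl2, Ccl7, Cxcl1 and Il6, so this clustering could not decide whether such cells form a state. Mean Ccl2 ran from 0.0938 to 0.330 over 10 fibroblast-like sub-clusters. Sub-cluster 4, with 0.330, had the highest Cxcl1 mean (3.39) and a Ccl7 mean of 0.734. Sub-cluster 6 had 0.238 with the highest Ccl7 mean (2.02), and sub-cluster 9 had 0.271 with the lowest (0.0593). A few fibroblast-like cells with Ccl2 were therefore seen, and as a group they had higher means of Ccl7 and Cxcl1. Cells holding all of these genes were not counted, and whether the few cells form a state stays open. Whether they differ with genotype was not tested.

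MHC class II genes were higher in smooth-muscle-like than in fibroblast-like cells. The tables argue against macrophage RNA as the whole source, since the median ratio of the 7 genes to C1qa was 11.9 times that of macrophage-like cells (9.86 and 14.7 in the sets), and 0 of 484 smooth-muscle-like cells with Cd74 of 3 or more (0%, upper limit 0.759%) reached the summed value of 10 for the macrophage genes. These cells were 6.03% of the class, 4.68% in set 1 and 7.82% in set 2. The depth adjustment before deposit could have altered ratios gene by gene and was not tested. Free RNA or doublets of cluster 4, which carried more MHC class II than either class, were also not tested, and no biological explanation was tested.

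Smooth-muscle-like sub-clusters divided by barcode set, with set 1 giving from 14.7 to 93.9% of their cells, and the association (Cramer's V from 0 to 1) was 0.532 over all cells when clustered without the list genes (0.470 to 0.542 over 10 seeds), against 0.111 in fibroblast-like cells (0.111 to 0.220). Sex-linked genes alone are unlikely to be the source, since V was 0.521 without them (0.508 to 0.553 over 10 seeds) and 0.562 with all genes (0.510 to 0.593). A remaining depth difference cannot be told apart. Among 1210 cells in a narrow window of totals above 11000, 615 of them from set 1, V was 0.432. Its ratio to that over all cells ran from 0.748 to 1.05 over seeds. These are adjusted totals, so the window did not hold the original depth equal and could not test it. Library preparation, the animals pooled, their sex and their genotype all stay open, since neither set was assigned to a library.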
